A study of Mus musculus with 18 samples.

How the data were processed

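RNA was measured by polyA RNA-seq in 18 libraries, 3 (replicates A, B and C) for each of days 0, 1, 2, 4, 7 and 14 of culture. Per the labels' protocols, tubules were released from kidneys of 6-week-old female C57BL/6J mice with collagenase, enriched on a Percoll gradient, plated on tissue culture plastic and grown for up to 14 days without subculture, and RNA was extracted with RNeasy kits. Day and replicate were taken from the labels.

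A table of estimated counts per gene, whole numbers as deposited, and a table of TPM (transcripts-per-million) per gene were deposited by the authors. The TPM of each library have the same sum, so they hold no depth. Per the submitters' processing notes, the tools were cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 with the GRCm38 genome. The annotation release and the strandedness of the counting are not given in the sources used here, so genes that overlap or are antisense to each other can share reads, and reads of near-identical copies can be split among them. The tables hold 55426 entries. The 5 reporter transgenes, with 0 counts in every library, were left out, leaving 55421 genes. In 878 cells the estimated count was 0 beside a TPM above 0. Of the gene IDs, 55154 were found in GENCODE vM21 (GRCm38), from which positions were taken, as were 18734 of the tested IDs, 18468 of them under the same name.

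No pair of libraries of a day held identical values or differed as little as sampling noise (chi-square per degree of freedom of at least 7.03). CPM were computed from the deposited estimated counts with TMM-scaled library sizes, and log2 CPM with a prior count of 2. The filterByExpr rule of edgeR left 18754 genes. Differences were tested with edgeR's quasi-likelihood F test in 1 model of the 6 day means over all 18 libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were taken as the fold change over the root of F. For a day with 0 counts in all 3 libraries, folds were computed against a floor of 3 counts over these libraries, and for 1 to 3 counts as a ratio with an exact 95% interval. The distance of a library was its mean absolute log2 CPM difference from the mean of day 0 (for a day 0 library, of the other 2).

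Before the data were examined, the comparisons, tests and alternatives, 44 gene lists and the rule for named genes were fixed. Of the 833 list genes, 832 were matched by name and 1 by a synonym, and 805 were tested. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison), with camera at an estimated correlation and with fry beside it. The named genes are 22 genes fixed whatever their values; the 10 largest rises and falls of day 1 and day 14 against day 0 and the 5 largest of each other comparison, among called genes with at least 10 CPM in the higher day, no overlap of the libraries and a gene symbol; up to 3 members of a list with the smallest adjusted p in the direction of most calls and 2 in the other; and the 5 genes per direction that turned back most. Not each gene so found is printed, and some of them are not reported here.

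The alternatives were DESeq2 size factors, library sizes alone, mitochondrially encoded genes left out, no filter on low counts, the replicate letter as a block, only the libraries of the days compared, glmTreat against a fold of 2, the DESeq2 Wald test, limma-trend on log2(TPM + 1) with a mean TPM of at least 0.5, on log2(TPM + 0.1) and on log2(TPM + 1) without that filter, a prior count of 0.5, and each library left out in turn. A range over the alternatives covers 22 fits for a list (scalings, block and libraries left out) and 29 for a gene. Against TMM, library sizes alone moved the median log2 fold change of all genes by 0.3, 0.51, 0.49, 0.5 and 0.56 on days 1, 2, 4, 7 and 14 against day 0 and by 0.21 on day 2 against day 1. The values for limma on log2(TPM + 1) were 0.35, 0.55, 0.61, 0.66, 0.77 and 0.21, with 0.11 on day 14 against day 7, and leaving out mitochondrially encoded genes moved day 4 against day 0 by 0.11. Changes are given relative to TMM.

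Counts of 18210 genes were simulated for day 1 against day 0. Of 50 each changed 1.5, 2, 4 and 8-fold, the test found 8, 34, 44 and 48, and it called 8 unchanged genes. With none changed for day 14 against day 7, it called 0. Few genes were changed, so scaling was not tested, nor was the real spread. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.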

Results

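RNA was sequenced from mouse kidney proximal tubules and from the cells that grew from them in primary culture. The 18 libraries fall into 6 days of 3 libraries each (replicates A, B and C): day 0, the day of isolation, and days 1, 2, 4, 7 and 14 of culture without subculture. The proximal tubule is the nephron segment behind the glomerulus, which reabsorbs most of the filtered salt, glucose, amino acids and protein and secretes organic anions and drugs. Transcript levels were compared between isolation and culture, and between consecutive sampled days. Totals of estimated counts per library ran from 23799559 to 37579097. Levels are given as counts-per-million (CPM), mean±SD over the 3 libraries of a day. Mitochondrially encoded transcripts took 4.92±0.914% of the counts on day 0, 4.13±0.724% on day 1, 1.69±0.182% on day 2, 0.466±0.0300% on day 4, 0.807±0.118% on day 7 and 0.932±0.0639% on day 14 (SD, n = 3 each). The labels call the replicates biological but do not say whether they came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

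The whole profile moved away from day 0 early and stayed apart. The mean absolute log2 CPM difference from the day 0 mean over 18754 genes was 0.262±0.0150 among the day 0 libraries themselves, 1.22±0.0790 on day 1, 1.44±0.0578 on day 2, 1.62±0.0246 on day 4, 1.47±0.0726 on day 7 and 1.48±0.00563 on day 14 (SD, n = 3 each). By two-sided exact permutation tests, p was 0.1 for each step up to day 7 and 1 for day 14 against day 7. It was also 0.1, the smallest that 3 libraries against 3 allow, for each culture day against day 0. Measuring from day 0 favours the latter. By an edgeR quasi-likelihood test of any difference among the 6 days, 16839 of 18754 genes (89.8%) passed at a Benjamini-Hochberg (BH) adjusted p of 0.05. Day 7 replicate C lay apart from A and B. Its correlations across genes with the day 4 libraries averaged r = 0.975, against 0.952 and 0.953 for A and B. Levels, list counts and medians of day 7 are therefore given without replicate C where that moves them by over 1.5 times.

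**Figure D1:**
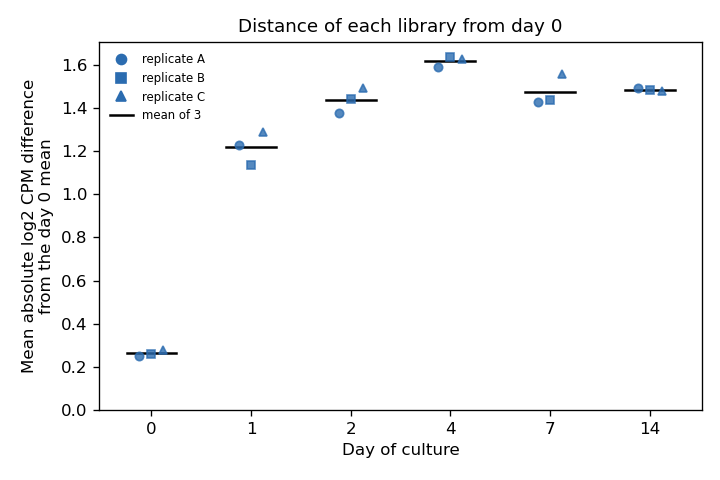
Mean absolute log2 CPM difference of each library from the day 0 mean (vertical axis, log2 units) by culture day (horizontal axis). Points are libraries, with a marker for each replicate letter, and black bars the mean of 3; a day 0 library is measured from the other 2, so that day sits at 0.262 while day 4 reaches 1.62.

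On day 1, against day 0, genes of proximal tubule transport fell and genes of tubule injury rose. Slc34a1, the apical sodium-phosphate cotransporter (ENSMUSG00000021490, chromosome 13, 55398187 to 55415592 in GRCm38), fell from 13750±911 to 3868±1350 CPM (SD, n = 3). Lrp2, the endocytic receptor megalin (ENSMUSG00000027070, chromosome 2, 69424340 to 69586065), fell from 495±120 to 158±63.3 CPM, and Pck1, an enzyme of gluconeogenesis, from 4249±1150 to 464±336 CPM. Havcr1, which encodes kidney injury molecule and is a standard marker of damaged proximal tubule (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), rose from 0.161±0.106 to 1680±527 CPM. Cdkn1a, a p53 target that arrests the cell cycle (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose from 7.78±3.03 to 538±60.9 CPM. The log2 fold changes of these genes were -1.83±0.31, -1.65±0.34, -3.20±0.52, 13.31±1.07 and 6.12±0.27 (SE), with an adjusted p of at most 0.000464 for each (edgeR quasi-likelihood, BH).

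Gene lists are described by their measured members, and where a single count is given, that over all genes tested and that adjusted over the list alone were the same. Of the proximal tubule transporters, 35 of 36 fell, with a median log2 fold change of -2.25: Slc5a2, the sodium-glucose cotransporter of the early tubule, went from 1827±125 to 649±173 CPM and Slc22a6, an organic anion transporter, from 772±92.7 to 165±63.1 CPM (SD, n = 3). Of the proximal tubule endocytosis list, 10 of 12 fell (Cubn, the receptor cubilin, from 249±85.6 to 66.6±30 CPM). Of the brush border enzymes and scaffold, 22 of 23 fell (Dpp4 from 206±18.7 to 44.7±12.2 CPM), and of the S1 and S2 segment markers all 8 fell. Of the S3 segment markers 6 of 7 fell (adjusted over the list alone, 23 lower in brush border enzymes and scaffold). For the transporters, endocytosis list, brush border list and S1 and S2 segment markers, camera (BH) gave adjusted p = 3.26e-06, 0.00949, 0.000244 and 0.0163, and p = 0.394, 0.394, 0.318 and 0.461 with an estimated correlation. The S3 segment markers had a camera adjusted p (BH) of 0.0739, and 0.049 or 0.048 without day 0 replicate B or day 2 replicate B (0.0472 to 0.117 over the alternatives).

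Genes of oxidative metabolism fell as well. Of the fatty acid oxidation list, 30 of 31 fell and 1 rose (Cpt2 from 259±29.2 to 38.9±8.11 CPM, and Pdk4, an inhibitor of glucose oxidation, from 44.5±19.0 to 137±59.8 CPM, SD, n = 3). Of the nuclear-encoded respiratory chain list, all 31 fell, with a median of -1.29, and of the mitochondrially encoded genes 11 of 13 fell. Of the gluconeogenesis list 8 of 9 fell (Fbp1 from 2554±356 to 559±234 CPM). Of the xenobiotic and steroid metabolism list, 35 of 38 fell and 1 rose: Cyp24a1, which inactivates vitamin D, went from 177±34.7 to 1.80±0.659 CPM. Of the glycolysis list, 14 of 18 rose and 1 fell: Pkm, the pyruvate kinase of proliferating cells, rose from 496±90.5 to 1636±22.5 CPM. Hk2, a hexokinase, reached 70.4±10.7 CPM against 2 counts over the day 0 libraries (ratio 2410, 95% interval 666 to 19900). For the fatty acid oxidation list, respiratory chain, mitochondrially encoded genes, gluconeogenesis list, xenobiotic list and glycolysis list, camera (BH) gave adjusted p = 3.6e-09, 1.22e-16, 0.0102, 0.0108, 0.000214 and 0.003, and p = 0.315, 0.253, 0.461, 0.386, 0.394 and 0.545 with an estimated correlation.

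Of the proximal tubule transcription factors, 14 of 15 fell and 1 rose. Hnf4a, a nuclear receptor that maintains the differentiated tubule (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910 in GRCm38), fell from 615±41.8 to 61.4±25 CPM, Maf from 146±7.00 to 10.4±3.98 CPM and Rxra from 162±8.18 to 75.3±6.26 CPM (SD, n = 3), while Pax8, a transcription factor of the whole nephron, rose from 111±13.8 to 285±16.3 CPM. For the transcription factors, camera (BH) gave adjusted p = 0.00225, and p = 0.221 with an estimated correlation. Of the nephron development list, 8 of 19 fell and 4 rose, including Lhx1 from 36.3±3.32 to 3.09±0.272 CPM and Notch2 from 18.02±3.12 to 43.2±0.634 CPM. Its median was -0.26, and 0.03 with scaling to library size only, where 6 rose and 8 fell. The camera adjusted p (BH) was 0.348.

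Of the tubule injury and dedifferentiation list, 29 of 34 rose and 2 fell, with a median of 4.13. Krt20, a keratin, rose from 0.106±0.0351 to 1048±270 CPM, Sox9, a transcription factor of regenerating tubule, from 2.96±0.651 to 56.1±8.77 CPM, and Lcn2, a secreted injury marker, from 1.93±1.5 to 29.8±7.81 CPM (SD, n = 3). Prom1 fell from 433±74.1 to 132±19.0 CPM. Of the failed-repair proximal tubule markers, 10 of 14 rose and 1 fell: Csf1, a macrophage growth factor, rose from 6.33±0.404 to 197±29.5 CPM, while Vcam1, the adhesion molecule of that state, had 5.03±0.515 CPM on day 0 and 4.98±0.610 CPM on day 1 (adjusted p = 0.976, edgeR quasi-likelihood, BH). Of the NF-kB and chemokines list, 29 of 35 rose and 4 fell (adjusted over the list alone, 30 higher in NF-kB and chemokines), with a median of 2.99, or 2.51 with members at 0 counts set to their bound. Rela, a subunit of the factor itself, rose from 42.3±0.463 to 250.4±14.4 CPM and Ccl2, a monocyte chemokine, from 0.248±0.280 to 1.84±0.428 CPM (adjusted p = 0.0555 and 0.0736 without day 0 replicates A or B and 0.000295 to 0.0736 over the alternatives, edgeR quasi-likelihood, BH). For the injury list, failed-repair markers and NF-kB list, camera (BH) gave adjusted p = 2.2e-29, 0.000244 and 3.85e-09, and p = 0.00204, 0.19 and 0.078 with an estimated correlation.

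Stress programs rose on day 1. Of the NRF2 targets, 17 of 19 rose and 1 fell: Hmox1, heme oxygenase, went from 37.6±4.15 to 3407±808 CPM (SD, n = 3). Of the p53 targets and senescence list, 17 of 23 rose and 3 fell (Mdm2 from 71.9±3.20 to 320±12.7 CPM), and of the integrated stress and unfolded protein response list 16 of 25 rose and 6 fell (Asns from 4.75±0.601 to 309±18.3 CPM). Of the heat shock list 13 of 16 rose and 1 fell (Hspb1 from 8.70±0.906 to 94.4±3.14 CPM). Of the immediate early genes, 15 of 29 rose and 5 fell: Fosl2 rose from 9.74±1.74 to 159±13.4 CPM and Fos fell from 409±225 to 64.6±31.9 CPM. Of the hypoxia list, 14 of 20 rose and 2 fell (P4ha1 from 60.6±2.67 to 349±32.9 CPM). Of the interferon response list, 20 of 30 rose and 1 fell, such as Cxcl10 from 2.29±0.0854 to 35.3±6.56 CPM. For the NRF2 targets, p53 list, stress response, heat shock list, immediate early genes, hypoxia list and interferon list, camera (BH) gave adjusted p = 3.92e-09, 1.38e-05, 0.00118, 0.000244, 3.74e-06, 0.0163 and 0.0367, and p = 0.078, 0.0153, 0.19, 0.3, 0.253, 0.61 and 0.698 with an estimated correlation. Without day 1 replicates A or C the interferon list had a camera adjusted p (BH) of 0.0831 or 0.0716, and 0.119 with library sizes alone (0.00114 to 0.119 over the alternatives).

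Of the YAP and TAZ target genes, 15 of 19 rose and 4 fell: Ankrd1, induced by mechanical load, went from 0.566±0.207 to 33.1±5.51 CPM (SD, n = 3). Of the extracellular matrix list, 19 of 34 rose and 7 fell: Lamb3, a laminin chain, rose from 1.00±0.215 to 86.4±16.8 CPM and Fn1, fibronectin, from 1.77±0.427 to 25.5±1.22 CPM, while Col1a2 fell from 7.86±1.64 to 1.19±0.472 CPM. Of the mesenchymal and cytoskeletal list, 15 of 25 rose and 5 fell, with Vim, the vimentin filament of mesenchymal and injured epithelial cells, going from 16.3±1.65 to 205±29.9 CPM and Myl9, a smooth muscle light chain, from 24.7±4.11 to 1.02±0.611 CPM. Of the tight and adherens junction list, 16 of 26 rose and 5 fell: Cldn1 rose from 41.5±9.10 to 302±11.7 CPM and Cldn2, the leaky claudin of the proximal tubule, fell from 926±87.2 to 58.1±23.1 CPM. Of the TGF-beta target genes, 7 of 16 rose and 7 fell, with a camera adjusted p (BH) of 0.529. For the YAP and TAZ targets, matrix list, mesenchymal list and junction list, camera (BH) gave adjusted p = 5.04e-08, 0.0151, 0.000756 and 0.00949, and p = 0.0441, 0.503, 0.503 and 0.394 with an estimated correlation.

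Of the DNA replication list, 13 of 25 rose and 1 fell (Pcna from 34.5±1.03 to 68.0±0.850 CPM, SD, n = 3). Of the mitosis list 1 of 28 rose and 4 fell, or 3 and 15 without day 7 replicate C. Mki67, the proliferation antigen, had 2.36±1.20 CPM on day 0 and 1.01±0.192 CPM on day 1, with adjusted p = 0.186 (edgeR quasi-likelihood, BH), and 0.0373 without day 7 replicate C (0.0373 to 0.953 over the alternatives). The camera adjusted p (BH) was 0.132 for DNA replication and 0.424 for mitosis, and for DNA replication 0.00751 without that library (0.00751 to 0.297 over the alternatives). Of the cholesterol synthesis list, 14 of 23 fell and 5 rose (Nsdhl from 97.9±5.26 to 25.03±4.98 CPM). For the cholesterol list, camera (BH) gave adjusted p = 0.0255, and p = 0.604 with an estimated correlation. Of the lysosome and autophagy list, 14 of 24 fell and 6 rose (adjusted over the list alone, 12 higher in DNA replication and 0 lower in mitosis), with a median of -0.54 and a mean of 0.02, while limma on log2(TPM + 1) called 11 higher and 9 lower. Gpnmb, a lysosomal glycoprotein, rose from 0.113±0.124 to 28.8±3.74 CPM. The camera adjusted p (BH) of the lysosome list was 0.533.

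Markers of the loop of Henle, distal convoluted tubule and collecting duct and of red blood cells fell on day 1 beside the proximal lists. Of the loop of Henle markers, all 9 fell, of the distal convoluted tubule markers 9 of 10 fell, of the principal cell markers all 12 fell and of the intercalated cell markers all 12 fell. Umod, uromodulin of the thick limb, went from 2090±283 to 104±39.9 CPM, and Aqp2, the vasopressin-regulated water channel, from 363±69.2 to 13.6±1.71 CPM (SD, n = 3). Of the red blood cell markers, all 6 fell (Hbb-bs, whose reads could be split with Hbb-bt, from 37.4±9.82 to 11.6±2.66 CPM). For the loop of Henle markers, distal convoluted tubule markers, principal cell markers, intercalated cell markers and red blood cell markers, camera (BH) gave adjusted p = 0.00777, 0.0119, 0.0012, 4.68e-05 and 0.0324, and p = 0.394, 0.459, 0.394, 0.078 and 0.394 with an estimated correlation. Of the macrophage and myeloid markers, 12 of 14 fell and 1 rose: C1qa went from 3.58±2.12 to 0.0716±0.0621 CPM and Cd68 from 1.94±1.38 to 38.4±2.40 CPM. Members higher and lower were 1 and 8 of 15 for fibroblast and pericyte markers, 1 and 10 of 12 for podocyte markers, 6 and 5 of 13 for parietal epithelium and thin limb markers, 0 and 2 of 3 for lymphocyte markers, 5 and 5 of 14 for general tubule epithelium and 6 and 3 of 15 for endothelial markers (adjusted over the list alone, 13 lower in macrophage and myeloid markers). The endothelial markers had a median of 0.18 and a mean of -0.09, and 5 of them were lower without day 7 replicate C. Under library size scaling, 1 of the lymphocyte markers was higher and 1 lower. For these lists and the macrophage and myeloid markers, the camera adjusted p (BH) lay between 0.0739 and 0.985. It was 0.0183 for the macrophage and myeloid markers without day 0 replicate B and 0.0313, 0.0481 and 0.0406 for the podocyte markers without day 0 replicate C, day 1 replicate B or day 2 replicate B (0.0112 to 0.108 and 0.0313 to 0.141 over the alternatives), and 0.0717 for the red blood cell markers without day 7 replicate C (0.0175 to 0.0717).

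Among the 10 largest rises on day 1, Fosl1, a subunit of the AP-1 transcription factor, had 0 counts in each day 0 library and 668±18.6 CPM on day 1 (SD, n = 3), at least 15200-fold higher against a floor of 3 counts over the 3 libraries. Against the same floor Sprr2h was at least 2510-fold higher, Prl2c2 at least 1410-fold higher, Cpa4 at least 816-fold higher and Mmp10, a matrix metalloproteinase, at least 749-fold higher. Reads of Sprr2h and Prl2c2 could be split among near-identical copies, which leaves their levels uncertain. Among the largest falls were Slc4a1 from 123±61.8 to 1.71±0.631 CPM, Bsnd, a chloride channel subunit, from 115±19.2 to 2.65±0.117 CPM, and Hsd11b2, the cortisol-inactivating enzyme of the distal nephron, from 211±56.2 to 5.33±0.459 CPM. In all 6208 genes were higher and 6949 lower on day 1 than on day 0 by the edgeR quasi-likelihood, BH test, so that 47.2% of the called genes were higher. With library sizes alone as the scaling, 7827 were higher and 5598 lower (58.3%), and limma on log2(TPM + 1) gave 7305 and 4559 (61.6%). Which direction held more genes turned with the scaling, the test or the libraries used in each comparison but day 7 against day 4. Intervals and floors cover counting error only.

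Day 2 against day 0 showed transport genes at lower levels and cell division genes above day 0. Slc34a1 fell from 13750±911 to 584±243 CPM (SD, n = 3) and Pck1 from 4249±1150 to 11.4±6.70 CPM. Rrm2, a subunit of ribonucleotide reductase, rose from 10.97±1.84 to 281±95.2 CPM, and Anln, an actin-binding protein, from 2.26±0.669 to 88.3±35.4 CPM. Of the mitosis list, all 28 rose, with a median of 4.37. Of the replication list, 24 of 25 rose. All 36 proximal tubule transporters fell (median -4.94). Of the respiratory chain list, all 31 fell. Of the injury list, 30 of 34 rose and 3 fell (Krt19 from 1.20±0.401 to 201±15.7 CPM). Of the matrix list 21 of 34 rose and 4 fell (Thbs1 from 71.5±1.62 to 539±171 CPM). Markers of the distal nephron stayed below day 0 beside the proximal genes, as in the loop of Henle markers, of which all 9 fell, and the intercalated cell markers, of which all 12 fell (adjusted over the list alone, 31 higher in injury). For the mitosis list, replication list, transporters, respiratory chain, injury list, matrix list, loop of Henle markers and intercalated cell markers, camera (BH) gave adjusted p = 3.69e-05, 1.23e-05, 1.74e-16, 3.85e-24, 4.29e-26, 0.000717, 0.00245 and 2.35e-06, and p = 0.482, 0.444, 0.113, 0.113, 0.00312, 0.335, 0.321 and 0.0751 with an estimated correlation. Il24, a cytokine, had 0 counts in each day 0 library and 41.6±4.2 CPM on day 2, at least 949-fold higher. G6pc, the last enzyme of gluconeogenesis, fell from 1133±231 to 1.86±0.790 CPM. In all 7289 genes were higher and 6619 lower than on day 0 (52.4% higher), against 9894 and 4802 (67.3%) with library sizes alone and 9432 and 3877 (70.9%) by limma on log2(TPM + 1).

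By day 4, transport genes were far below day 0 and cell division genes far above it. Slc34a1 fell from 13750±911 to 4.34±1.22 CPM (SD, n = 3) and Lrp2 from 495±120 to 12.5±3.77 CPM, while Mki67 rose from 2.36±1.20 to 118±15.2 CPM and Kif23, a kinesin of cytokinesis, from 1.76±0.540 to 183±9.85 CPM. All 36 proximal tubule transporters fell (median -8.66), and of the mitosis list all 28 rose (median 5.88). Of the replication list all 25 rose. Of the cholesterol list, 17 of 23 rose and 1 fell: Lss, the enzyme that makes lanosterol, went from 38.5±0.918 to 226±18 CPM. Of the injury list, 32 of 34 rose and 2 fell. Of the general tubule epithelium list 11 of 14 rose and 2 fell (Krt18, a keratin of simple epithelia, from 22.3±5.28 to 1862±117 CPM). Endothelial markers were lower, with 13 of 15 below day 0. Among the macrophage and myeloid markers, Cd74, an antigen-presentation chain, fell from 117±61.1 to 0.454±0.0743 CPM. For the transporters, mitosis list, replication list, cholesterol list, injury list, epithelium list and endothelial markers, camera (BH) gave adjusted p = 1.37e-24, 2.94e-07, 9.25e-07, 1.32e-07, 2.6e-25, 8.92e-05 and 0.02, and p = 0.0704, 0.36, 0.36, 0.211, 0.00443, 0.215 and 0.473 with an estimated correlation. Acmsd, an enzyme of tryptophan breakdown, had 415±52.6 CPM on day 0 and 0 counts in each day 4 library, at least 12500-fold lower. Ccl20, a chemokine, reached 504.3±91.3 CPM against 1 count on day 0 (ratio 34500, 95% interval 6190 to 1360000). In all 7145 genes were higher and 6895 lower (50.9% higher), against 9537 and 5161 (64.9%) with library sizes alone and 9610 and 3950 (70.9%) by limma on log2(TPM + 1).

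On day 7 the transport genes were far below day 0 while matrix and epithelial genes were above day 0. Slc34a1 fell from 13750±911 to 0.0537±0.0475 CPM (SD, n = 3) and Hnf4a from 615±41.8 to 5.11±5.43 CPM, where the day 7 mean was 1.97 CPM (n = 2) without replicate C. Thbs1, the matrix glycoprotein thrombospondin, rose from 71.5±1.62 to 3271±65.2 CPM, Sox11, a transcription factor of the developing nephron, from 0.161±0.113 to 36.6±5.52 CPM, and Lcn2 from 1.93±1.5 to 781±229 CPM. All 36 proximal tubule transporters fell (median -9.08), of the injury list 32 of 34 rose, and of the YAP and TAZ target genes 17 of 19 rose. Of the matrix list, 28 of 34 rose and 2 fell (5 lower without day 7 replicate C), of the general tubule epithelium list 12 of 14 rose and 1 fell (Krt8 from 113±2.40 to 1595±520 CPM), and of the mitosis list all 28 rose. Of the endothelial markers 14 of 15 fell. For the transporters, injury list, YAP and TAZ targets, matrix list, epithelium list, mitosis list and endothelial markers, camera (BH) gave adjusted p = 1.15e-31, 5.31e-30, 6.96e-11, 6.36e-08, 3.21e-06, 0.000124 and 0.0023, and p = 0.0497, 0.0018, 0.00778, 0.112, 0.132, 0.51 and 0.392 with an estimated correlation. Of the interferon list, 22 of 30 rose and 1 fell (Bst2 from 6.58±1.90 to 68.4±24.3 CPM). Of the hypoxia list, 11 of 20 rose and 2 fell, with Slc2a1, a glucose carrier, from 79.5±14.4 to 957±629 CPM. Their camera adjusted p (BH) was 0.108 and 0.136, and 0.0314 and 2.78e-05 without day 7 replicate C (0.0314 to 0.389 and 2.78e-05 to 0.324 over the alternatives, and 0.0464 for interferon without day 1 replicate B). Wnt7a, a secreted Wnt ligand, had 310.4±67.4 CPM on day 7 against 2 counts on day 0 (ratio 10600, 95% interval 2940 to 87600). In all 7060 genes were higher and 6028 lower (53.9% higher), against 10022 and 4224 (70.3%) with library sizes alone and 10337 and 3147 (76.7%) by limma on log2(TPM + 1). Without day 7 replicate C the counts were 7051 and 6198.

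**Figure D2:**
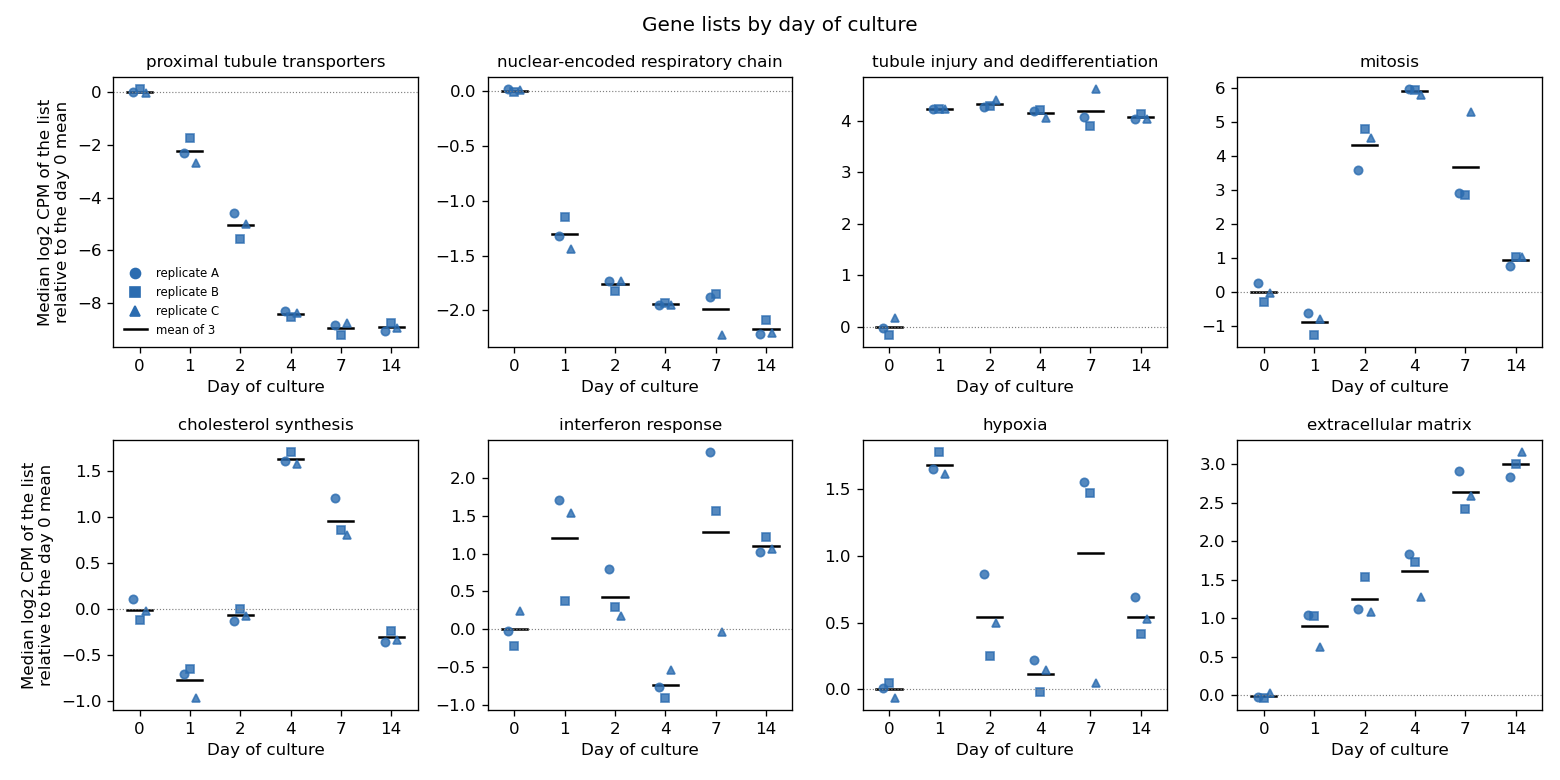
Median log2 change from the day 0 mean over the members of 8 gene lists (vertical axes, log2 units, each panel with its own scale) by culture day (horizontal axis). Points are libraries and black bars the mean of 3, which is -8.92 on day 14 for the proximal tubule transporters and 5.9 on day 4 for mitosis.

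After 14 days, against day 0, the genes of proximal tubule function were far below their starting level while injury, p53 target and epithelial junction genes were above day 0. Slc34a1 fell from 13750±911 to 0.507±0.316 CPM (SD, n = 3), Slc5a2 from 1827±125 to 0.0849±0.0880 CPM, Lrp2 from 495±120 to 10.5±5.11 CPM and Hnf4a from 615±41.8 to 1.12±0.487 CPM. Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252 in GRCm38) rose from 1.93±1.5 to 2192±12.7 CPM, Cdkn1a from 7.78±3.03 to 448±13.6 CPM, Fn1 from 1.77±0.427 to 448±147 CPM and Krt18 from 22.3±5.28 to 1284±24.9 CPM. Havcr1 rose from 0.161±0.106 to 119.8±31.2 CPM. The log2 fold changes of Slc34a1, Lrp2, Lcn2, Cdkn1a and Havcr1 were -14.69±0.54, -5.56±0.41, 10.21±0.44, 5.86±0.27 and 9.50±1.02 (SE), with an adjusted p of at most 4.44e-07 for each (edgeR quasi-likelihood, BH).

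All 36 proximal tubule transporters fell, with a median log2 fold change of -9.34: Slc2a2, the basolateral glucose carrier, went from 540.2±15.8 to 2.22±0.166 CPM (SD, n = 3), and Slc22a6 from 772±92.7 CPM to 3 counts over the day 14 libraries (ratio 23400, 95% interval 8010 to 114000). Of the proximal tubule endocytosis list, 9 of 12 fell and 2 rose (Dab2, an adaptor of megalin, from 1149±117 to 113±13.9 CPM, and Ap2a1, of the general clathrin adaptor, from 60.4±1.75 to 88.7±0.987 CPM). Of the brush border enzymes and scaffold, all 23 fell, and of the S1 and S2 segment markers all 8 fell. Of the S3 segment markers 5 of 7 fell and 2 rose (Slc5a1 from 156±1.70 to 1.88±0.717 CPM). Of the proximal tubule transcription factors, 13 of 15 fell and 1 rose: Maf went from 146±7.00 to 2.24±0.394 CPM and Pax8 from 111±13.8 to 316±17.2 CPM. For the transporters, endocytosis list, brush border list, S1 and S2 segment markers, S3 segment markers and transcription factors, camera (BH) gave adjusted p = 8.1e-31, 7.54e-06, 1.12e-14, 3.19e-13, 0.00499 and 1.61e-05, and p = 0.044, 0.124, 0.044, 0.044, 0.108 and 0.0625 with an estimated correlation.

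Metabolic genes stayed low. Of the fatty acid oxidation list, 30 of 31 fell (Acsl1 from 757±51.1 to 31.4±2.15 CPM, SD, n = 3), and of the respiratory chain list all 31 fell with a median of -2.18 (Ndufa4 from 653±8.81 to 127±7.38 CPM). Of the mitochondrially encoded genes all 13 fell. Of the gluconeogenesis list, 8 of 9 fell and 1 rose: Fbp1 went from 2554±356 to 0.220±0.123 CPM and Pck2, the mitochondrial counterpart of Pck1, from 27.8±0.296 to 152±6.36 CPM. Of the xenobiotic and steroid metabolism list, 35 of 38 fell and 1 rose: Miox, an oxygenase of the proximal tubule, fell from 5561±344 to 0.101±0.0731 CPM and Ephx1, an epoxide hydrolase, rose from 47.7±5.46 to 229±3.75 CPM. For the fatty acid oxidation list, respiratory chain, mitochondrially encoded genes, gluconeogenesis list and xenobiotic list, camera (BH) gave adjusted p = 2.64e-18, 2.18e-33, 3.43e-14, 2.81e-08 and 4.19e-19, and p = 0.0997, 0.0536, 0.0449, 0.049 and 0.049 with an estimated correlation. Of the glycolysis list, 8 of 18 rose and 4 fell, with a median of 0.06 that turned to -0.05 with DESeq2 size factors and a camera adjusted p (BH) of 0.153. Hk2 had 123±6.85 CPM against 2 counts on day 0 (ratio 4210, 95% interval 1170 to 34800).

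Of the injury list, 30 of 34 rose (Krt19 from 1.20±0.401 to 288±6.70 CPM, Sox9 from 2.96±0.651 to 134±7.62 CPM, SD, n = 3). Of the p53 list, 19 of 23 rose and 3 fell: Cdkn2b, a cyclin-dependent kinase inhibitor, went from 0.952±0.483 to 118±4.83 CPM and Plk2 from 13.7±2.19 to 729±39.2 CPM, while Glb1, the lysosomal beta-galactosidase, went from 197±6.73 to 68.4±1.34 CPM. Of the YAP and TAZ target genes, 18 of 19 rose and 1 fell (Ankrd1 from 0.566±0.207 to 428±34.4 CPM). Of the failed-repair proximal tubule markers, 8 of 14 rose and 4 fell, with Csf1 from 6.33±0.404 to 162±22.3 CPM and Vcam1 from 5.03±0.515 to 2.40±0.918 CPM. The adjusted p of Vcam1 was 0.0475 (edgeR quasi-likelihood, BH), above 0.05 without any 1 of 14 of the 18 libraries (0.0521 to 0.212), and 0.00257 to 0.868 over the alternatives. Of the NF-kB and chemokines list, 22 of 35 rose and 4 fell (Lif from 0.409±0.114 to 61.5±5.62 CPM, Il18 from 2.62±0.276 to 0.547±0.188 CPM), with a median of 1.76, or 1.63 at the bounds. Ccl2 had 0.248±0.280 CPM on day 0 and 0.780±0.299 CPM on day 14 (adjusted p = 0.165, and 0.0236 without day 7 replicate C and 0.00999 to 0.406 over the alternatives, edgeR quasi-likelihood, BH). Of the immediate early genes, 14 of 29 rose and 9 fell (Fos from 409±225 to 13.8±1.43 CPM). Of the stress response list, 14 of 25 rose and 7 fell, with Asns going from 4.75±0.601 to 455±27.7 CPM. For the injury list, p53 list, YAP and TAZ targets, failed-repair markers, NF-kB list, immediate early genes and stress response, camera (BH) gave adjusted p = 2.58e-27, 5.02e-09, 1.18e-11, 0.0074, 8.38e-05, 0.0364 and 0.00883, and p = 0.00168, 0.00168, 0.00785, 0.192, 0.125, 0.537 and 0.166 with an estimated correlation. The camera adjusted p (BH) of the immediate early genes was 0.0711 or 0.141 without day 0 replicates A or C, and 0.0574 with library sizes alone (0.0178 to 0.141 over the alternatives).

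Of the matrix list, 26 of 34 rose and 2 fell (Lamb3 from 1.00±0.215 to 212±12.1 CPM, Tgfbi from 2.90±0.425 to 0.111±0.0404 CPM, SD, n = 3). Of the mesenchymal list, 16 of 25 rose and 3 fell: Flna, an actin-binding protein, went from 42.4±2.93 to 1421±94.2 CPM, and Zeb1, a transcription factor of mesenchymal cells, from 5.51±0.376 to 0.568±0.133 CPM. Vim had 16.3±1.65 CPM on day 0 and 20.8±7.14 CPM on day 14 (adjusted p = 0.645, edgeR quasi-likelihood, BH). Of the junction list, 21 of 26 rose and 3 fell: Cldn3 and Cldn7 went from 8.01±0.911 to 197±2.63 CPM and from 36.4±5.33 to 374±18.5 CPM, and Cldn2 and Cldn10 from 926±87.2 to 13.6±1.84 CPM and from 208±37.7 to 0.845±0.618 CPM. Of the general tubule epithelium list, 12 of 14 rose and 1 fell (Cdh16 from 1502±62.2 to 702±10.9 CPM, with adjusted p = 0.196 by limma on log2(TPM + 1) and 4.15e-09 to 0.309 over the alternatives). Of the parietal epithelium and thin limb markers, 9 of 13 rose and 3 fell (adjusted over the list alone, 17 higher in mesenchymal), with Akap12 going from 5.96±1.42 to 556±19.4 CPM and Aqp1, a water channel, from 679±15.1 to 8.49±5.05 CPM. For the matrix list, mesenchymal list, junction list, epithelium list and parietal epithelium and thin limb markers, camera (BH) gave adjusted p = 1.39e-08, 3.81e-06, 2.04e-06, 6.24e-06 and 0.0129, and p = 0.106, 0.335, 0.101, 0.153 and 0.153 with an estimated correlation. With library sizes alone the last of these was 0.103 with the preset correlation (0.00313 to 0.103 over the alternatives).

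Camera did not pass for 10 further lists of cell state on day 14. Of the development list, 9 of 19 rose and 4 fell (Sox11 from 0.161±0.113 to 45.7±4.15 CPM, SD, n = 3). Of the TGF-beta target genes 10 of 16 rose and 5 fell (Pmepa1 from 30.1±4.67 to 353±18.7 CPM, Id1 from 27.4±7.21 to 3.61±0.311 CPM). Members higher and lower were 8 and 5 of 16 for heat shock, 8 and 2 of 25 for DNA replication (15 and 4 without day 7 replicate C), 7 and 0 of 28 for mitosis (19 and 0 without it), 18 and 2 of 30 for interferon response, 10 and 6 of 20 for hypoxia, 9 and 8 of 19 for NRF2 targets, 9 and 11 of 23 for cholesterol synthesis and 6 and 15 of 24 for lysosome and autophagy (adjusted over the list alone, 5 higher in mitosis and 12 lower in cholesterol synthesis). Gpnmb rose from 0.113±0.124 to 86.6±4.84 CPM and Slc2a1 from 79.5±14.4 to 897±179 CPM, while Me1, malic enzyme, fell from 544±27.9 to 227±11.6 CPM. The median log2 fold change of cholesterol synthesis was -0.31, and 0.24 with library sizes alone, where 11 rose and 8 fell. That of lysosome and autophagy was -0.62, and 0.24 by limma on log2(TPM + 1), where 12 rose and 10 fell, and the NRF2 targets median of 0.09 was -0.02 with DESeq2 size factors. Across the 10 lists the camera adjusted p (BH) lay between 0.141 and 0.449.

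Most markers of the loop of Henle, distal convoluted tubule and collecting duct and of endothelial, myeloid and red blood cells were below day 0 on day 14. Of the loop of Henle markers, 8 of 9 fell (Umod from 2090±283 to 2.25±0.364 CPM, SD, n = 3), of the distal convoluted tubule markers 8 of 10 fell, and of the principal cell markers 9 of 12 fell and 2 rose (Aqp3 from 239.6±37.5 to 1.304±0.378 CPM, Gata3 from 37.1±3.79 to 115±6.45 CPM). Of the intercalated cell markers 11 of 12 fell, with a median of -11.34, or -11.01 at the bounds. Of the endothelial markers, all 15 fell (Cldn5 from 6.85±0.5 to 0.459±0.0991 CPM), and of the macrophage and myeloid markers 10 of 14 fell and 1 rose (Cd74 from 117±61.1 to 0.249±0.216 CPM). Of the red blood cell markers all 6 fell, with a median of -11.84, or -8.95 at the bounds. For the loop of Henle markers, distal convoluted tubule markers, principal cell markers, intercalated cell markers, endothelial markers, macrophage and myeloid markers and red blood cell markers, camera (BH) gave adjusted p = 0.004, 4.03e-05, 0.00497, 2.1e-10, 1.97e-05, 0.0346 and 1.02e-05, and p = 0.323, 0.169, 0.367, 0.0116, 0.241, 0.456 and 0.0587 with an estimated correlation. Of the fibroblast and pericyte markers, 9 of 15 fell and 5 rose (Rgs5, of pericytes, from 23.8±5.97 to 0.301±0.105 CPM, and Col1a1, a collagen chain, from 0.897±0.779 to 74.6±13.9 CPM), and of the podocyte markers 9 of 12 fell and 2 rose. Of the lymphocyte markers 2 of 3 fell and 1 rose. The camera adjusted p (BH) of these 3 lists was 0.21, 0.0833 and 0.967 (for the podocyte markers 0.0422 without day 0 replicate C and 0.0422 to 0.11 over the alternatives). By limma on log2(TPM + 1), 1 of the lymphocyte markers rose and 0 fell.

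Among the largest falls of day 14, Klk1, a tissue kallikrein, had 2372±296 CPM on day 0 (SD, n = 3) and 0 counts in each day 14 library, at least 71900-fold lower, and against the same floor Akr1c21, a steroid dehydrogenase, was at least 50400-fold lower, Slc22a8, an organic anion transporter, at least 48200-fold lower, and Spp2 at least 28600-fold lower. Among the largest rises, Wnt7a had 427±28.2 CPM (ratio 14600, 95% interval 4040 to 120000), Sema3a, a secreted guidance protein, was at least 447-fold higher, and Areg, a ligand of the EGF receptor, at least 297-fold higher. Msln, mesothelin, rose from 0.165±0.213 to 459±37.4 CPM and Igfbp2, a growth factor binding protein, from 0.269±0.304 to 635±126 CPM. In all 7007 genes were higher and 6026 lower than on day 0 (53.8% higher) by the edgeR quasi-likelihood, BH test. With library sizes alone the counts were 10373 and 4047 (71.9%), and by limma on log2(TPM + 1) 10791 and 2891 (78.9%).

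**Figure D3:**
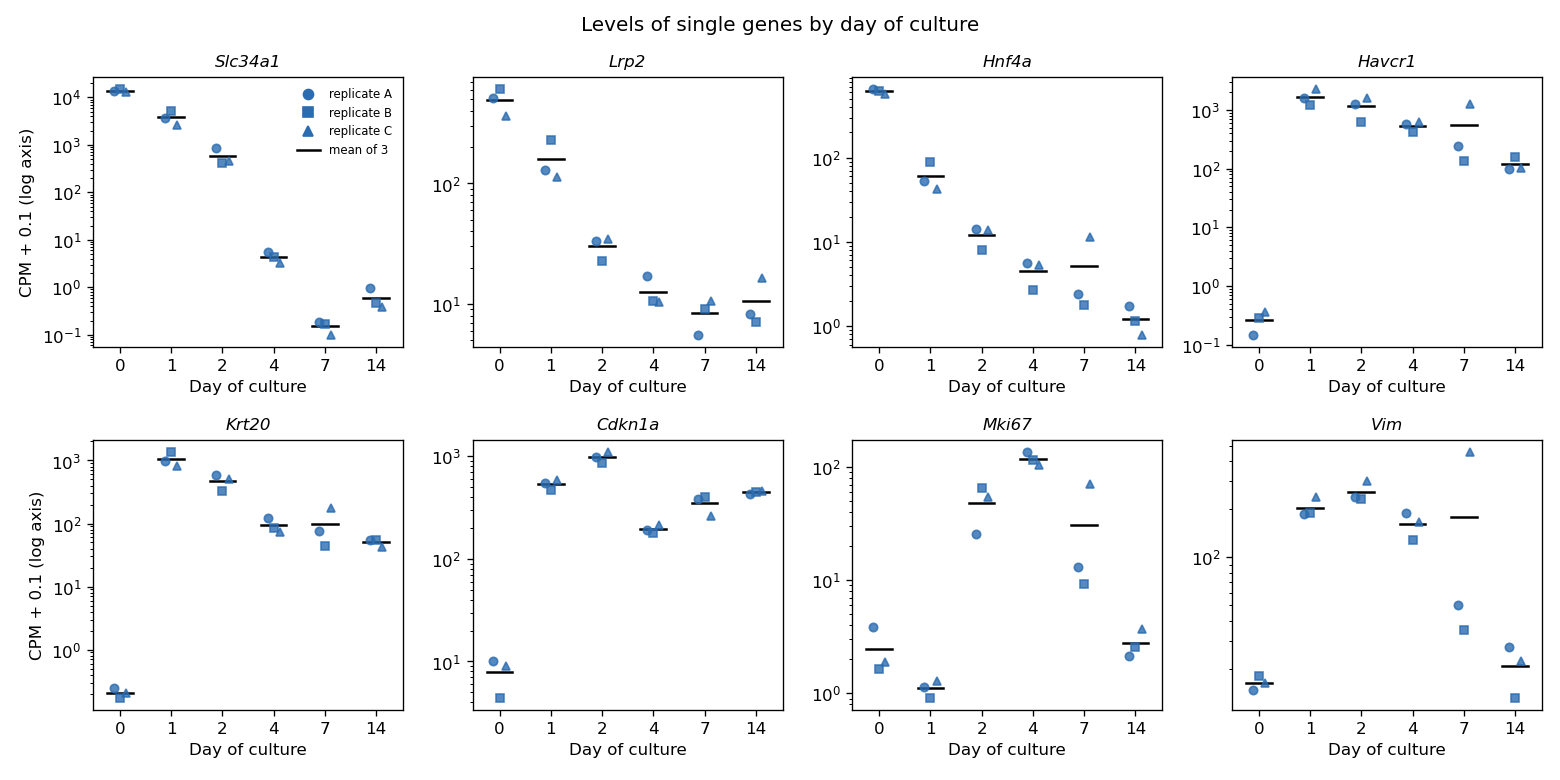
Levels of Slc34a1, Lrp2, Hnf4a, Havcr1, Krt20, Cdkn1a, Mki67 and Vim by culture day (horizontal axis), as CPM + 0.1 on a log axis (vertical). Points are libraries and black bars the mean of 3; Slc34a1 runs from 13750 CPM on day 0 to 0.506 CPM on day 14, and Havcr1 from 0.161 CPM on day 0 to 1680 CPM on day 1.

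The step from day 1 to day 2 brought the genes of the cell cycle. Rrm2 rose from 15.2±5.17 to 281±95.2 CPM (SD, n = 3), Top2a, the topoisomerase of dividing cells, from 1.27±0.582 to 75.2±26.4 CPM, Cdk1, the mitotic kinase, from 1.64±0.858 to 61.1±22.6 CPM, and Mki67 from 1.01±0.192 to 48.3±20.2 CPM. Of the mitosis list, 27 of 28 rose, with a median log2 fold change of 5.37. Of the replication list, 24 of 25 rose (median 1.95). For the mitosis list and replication list, camera (BH) gave adjusted p = 2.13e-29 and 1.41e-16, and p = 0.102 and 0.193 with an estimated correlation. Some stress genes of day 1 fell back: of the hypoxia list, 14 of 20 fell (P4ha1 from 349±32.9 to 99.0±31.4 CPM), and of the interferon list 14 of 30 fell (Cxcl10 from 35.3±6.56 to 7.55±2.24 CPM). Of the NRF2 targets 12 of 19 fell and 1 rose (Hmox1 from 3407±808 to 1011±164 CPM). For the hypoxia list, interferon list and NRF2 targets, camera (BH) gave adjusted p = 9.45e-06, 0.00169 and 1.53e-05, and p = 0.48, 0.609 and 0.129 with an estimated correlation. Of the p53 list, 13 of 23 rose and 3 fell (adjusted over the list alone, 28 higher in mitosis, 25 higher in DNA replication, 17 lower in hypoxia, 16 lower in interferon response and 14 lower in NRF2 targets), with Ccng1 going from 344±41.2 to 817±44.8 CPM. For the p53 list, camera (BH) gave adjusted p = 9.94e-05, and p = 0.0363 with an estimated correlation.

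Transport genes went on falling between days 1 and 2: of the proximal tubule transporters, 35 of 36 fell (Slc34a1 from 3868±1350 to 584±243 CPM, SD, n = 3). Of the mitochondrially encoded genes 12 of 13 fell, beside a fall of their share of counts from 4.13% to 1.69%. Of the cholesterol list, 13 of 23 rose and 3 fell (Idi1 from 51.5±4.73 to 135±27.6 CPM). Of the intercalated cell markers, 9 of 12 fell. Of the red blood cell markers, all 6 fell (adjusted over the list alone, 13 lower in mitochondrially encoded and 14 higher in cholesterol synthesis). For the transporters, mitochondrially encoded genes, cholesterol list, intercalated cell markers and red blood cell markers, camera (BH) gave adjusted p = 2e-36, 8.41e-15, 0.000314, 0.000314 and 1.9e-08, and p = 0.0363, 0.0459, 0.503, 0.0839 and 0.0363 with an estimated correlation. The largest rises included Cenpf, a kinetochore protein, from 0.176±0.00509 to 20.8±9.77 CPM, and Ube2c from 0.729±0.260 to 47.4±21.5 CPM, and the largest falls Cndp1 from 10.7±5.32 to 0.197±0.170 CPM and Pck1 from 464±336 to 11.4±6.70 CPM. In all 3186 genes were higher and 3283 lower on day 2 than on day 1 (49.3% higher), against 5492 and 2185 (71.5%) with library sizes alone and 5288 and 1832 (74.3%) by limma on log2(TPM + 1).

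From day 2 to day 4 cholesterol synthesis genes rose together and the remaining transport genes fell. Idi1, an isomerase of the mevalonate pathway, rose from 135±27.6 to 663±49.7 CPM (SD, n = 3) and Scd1, a fatty acid desaturase, from 11.8±2.07 to 204±14.2 CPM. Of the cholesterol list, 22 of 23 rose, with a median log2 fold change of 2.00. Of the proximal tubule transporters, 33 of 36 fell (Slc34a1 from 584±243 to 4.34±1.22 CPM, Slc5a2 from 179.5±50.9 to 3.05±0.867 CPM), and of the S1 and S2 segment markers 7 of 8 fell. Of the mitochondrially encoded genes all 13 fell. Of the mitosis list, 26 of 28 rose (Ccnb2 from 16.8±8.07 to 92.2±2.78 CPM). Of the general tubule epithelium list, 10 of 14 rose (Esrp1, an epithelial splicing factor, from 23.3±5.22 to 66.8±1.44 CPM). Of the lysosome list, 14 of 24 fell and 2 rose (adjusted over the list alone, 28 higher in mitosis), with Sqstm1 going from 3616±354 to 1436±91.9 CPM. For the cholesterol list, transporters, S1 and S2 segment markers, mitochondrially encoded genes, mitosis list, epithelium list and lysosome list, camera (BH) gave adjusted p = 5.09e-45, 1.51e-28, 6.3e-16, 7.89e-22, 2.9e-06, 1.53e-05 and 0.000127, and p = 0.0191, 0.0748, 0.0371, 0.0191, 0.588, 0.348 and 0.423 with an estimated correlation.

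Lcn2 rose from 32.7±2.13 to 146±21.5 CPM (SD, n = 3) and Cdkn1a fell from 982±120 to 195±16.3 CPM between days 2 and 4. Of the p53 list, 12 of 23 fell and 6 rose, with a camera adjusted p (BH) of 0.0637, and 0.0224 to 0.0484 without day 0 replicates B or C, day 1 replicates A or B or day 2 replicate C (0.0224 to 0.114 over the alternatives). Intercalated cell and endothelial markers fell beside the transport genes: of the intercalated cell markers, 10 of 12 fell, with a median of -3.24, or -2.99 at the bounds. Of the endothelial markers, 13 of 15 fell (adjusted over the list alone, 11 lower in intercalated cell markers), with Flt1, a receptor of vascular growth factor, going from 10.2±1.84 to 2.59±0.373 CPM. For the intercalated cell markers and endothelial markers, camera (BH) gave adjusted p = 2.52e-08 and 0.000127, and p = 0.0191 and 0.401 with an estimated correlation. The largest rises included Plekhs1 from 0.731±0.286 to 23.1±3.51 CPM and Foxj1, the factor of motile cilia, from 0.707±0.246 to 11.8±2.28 CPM, and the largest falls Ces1d from 22.8±5.43 to 0.0987±0.0553 CPM and Slc22a8 from 53.2±17.7 to 0.320±0.0364 CPM. In all 3633 genes were higher and 4138 lower on day 4 than on day 2 (46.8% higher). Without mitochondrially encoded genes there were 4368 and 3618, without day 2 replicate A 3587 and 2900, and without day 14 replicates A, B or C 4226 and 3538, 4228 and 3534 and 4199 and 3512.

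From day 4 to day 7 interferon and hypoxia genes rose and cell division genes fell. B2m, a subunit of class I antigen presentation, rose from 132±20.7 to 267±41.2 CPM (SD, n = 3), Ifit2, an interferon-induced protein, from 8.70±1.89 to 49.0±32.1 CPM, P4ha1, a collagen prolyl hydroxylase, from 66.7±8.31 to 161±55.8 CPM, and Col1a1 from 2.88±0.768 to 37.0±13.3 CPM. Rrm2 fell from 705±44.5 to 207±113 CPM and Nqo1, a quinone reductase, from 191±18.3 to 50.4±6.57 CPM. Of the interferon list, 27 of 30 rose (median 1.99), and of the hypoxia list 18 of 20 rose (median 1.57). Of the matrix list 21 of 34 rose and 3 fell. Of the mitosis list, all 28 fell (median -1.73, or -3.04 without day 7 replicate C), of the replication list 23 of 25 fell (median -1.32, or -2.24 without it), of the NRF2 targets 17 of 19 fell and of the cholesterol list 17 of 23 fell and 1 rose (Idi1 from 663±49.7 to 281±24.6 CPM). Of the lysosome list, 19 of 24 rose (Map1lc3a from 26.4±0.910 to 70.3±17.4 CPM). Of the development list 11 of 19 rose (adjusted over the list alone, 28 higher in interferon response, 4 lower in extracellular matrix, 24 lower in DNA replication, 18 lower in NRF2 targets, 1 lower in lysosome and autophagy and 14 higher in nephron development), with Sox11 going from 9.81±1.19 to 36.6±5.52 CPM. The medians of the interferon list relative to day 0 were 2.33, 1.56 and -0.04 in day 7 replicates A, B and C and -0.90 to -0.53 in the day 4 libraries, and those of the hypoxia list 1.55, 1.47 and 0.05 and -0.02 to 0.22, so that replicate C lay below A and B in both, for hypoxia within the day 4 range. For the interferon list, hypoxia list, matrix list, mitosis list, replication list, NRF2 targets, cholesterol list, lysosome list and development list, camera (BH) gave adjusted p = 1.12e-07, 2.78e-05, 0.000828, 3.43e-10, 1.27e-10, 2.1e-17, 2.51e-09, 2.46e-09 and 0.000828, and p = 0.699, 0.757, 0.562, 0.562, 0.56, 0.0474, 0.43, 0.337 and 0.227 with an estimated correlation.

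Of the p53 list, 13 of 23 rose and 3 fell (Btg2 from 61.2±1.29 to 192±59.6 CPM, SD, n = 3), and of the stress response list 12 of 25 fell and 3 rose (Slc7a11, the cystine carrier, from 139±22.7 to 24.7±14.4 CPM). Of the mitochondrially encoded genes 10 of 13 rose. Of the principal cell markers, 7 of 12 rose and 1 fell (adjusted over the list alone, 14 higher in p53 and 4 higher and 15 lower in stress response), with Hsd11b2 going from 2.45±0.756 to 7.81±3.33 CPM. For the p53 list, stress response, mitochondrially encoded genes and principal cell markers, camera (BH) gave adjusted p = 0.000828, 0.000828, 0.000128 and 0.0155, and p = 0.0726, 0.302, 0.501 and 0.757 with an estimated correlation. The largest rises included Tgtp1, an interferon-induced GTPase, from 0.426±0.211 to 16.6±15.2 CPM, Igfbp2 from 1.39±0.336 to 50.5±37.2 CPM and Dhrs3, a retinal reductase, from 3.86±0.580 to 95.3±70.8 CPM, and the largest falls Gsta1 from 252±29.3 to 15.6±13.5 CPM (7.84 CPM on day 7 without replicate C) and Ccl20 from 504.3±91.3 to 41.4±14.0 CPM. In all 4122 genes were higher and 2985 lower on day 7 than on day 4, and 5387 and 4148 without day 7 replicate C (1680 and 775 by at least 2-fold, 2218 and 1599 without C, and 453 and 486 lower without A and B). A fit of only the 6 libraries of these days called 1918 and 1691. Without replicate C the camera adjusted p (BH) of the matrix list was 0.263 (1.26e-05 to 0.263 over the alternatives), with 18 higher and 11 lower (counted after seeing the data). Without day 7 replicate B that of the principal cell markers was 0.087 (1.54e-05 to 0.087). Without replicate C 10 of the endothelial markers were lower, against 2 with it, and 17 of the NF-kB and chemokines members, against 9, while 5 of the stress response list were higher, against 3, and 14 members of the junction list were higher, against 8. The mesenchymal list had 7 higher and 2 lower with all libraries and 5 higher and 9 lower without it, with a camera adjusted p of 0.377, and of 0.0301 or 0.0236 without replicates A or B (0.0236 to 0.477 over the alternatives). That of the endothelial markers, NF-kB and chemokines and junction lists was 0.191, 0.122 and 0.122, and 0.0052, 0.0363 and 0.0135 without replicate C (up to 0.39, 0.258 and 0.245 over the alternatives).

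**Figure D4:**
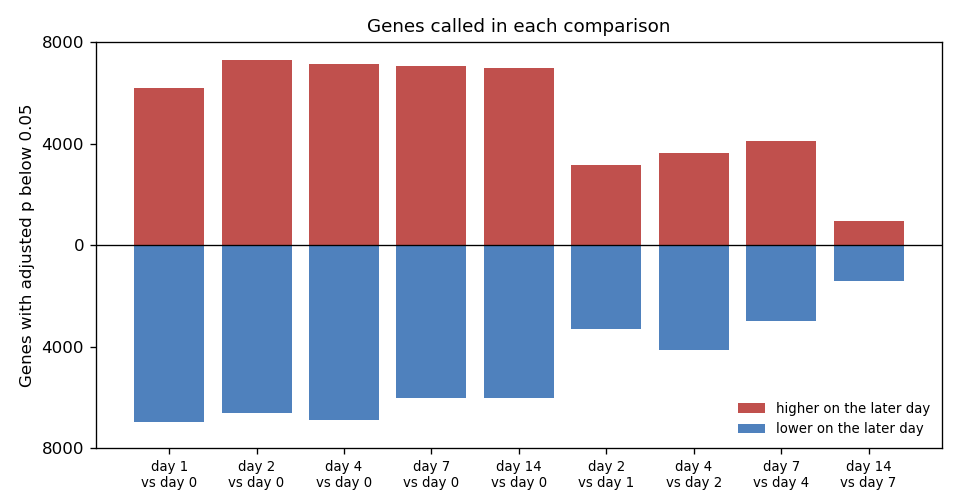
Genes called higher (above 0) and lower (below 0) in each comparison (horizontal axis), as the number of genes at a BH adjusted p of 0.05 by edgeR quasi-likelihood (vertical axis). Day 14 against day 7 has 950 higher and 1399 lower, the fewest of the 9 comparisons.

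From day 7 to day 14 cell division and cholesterol synthesis genes fell. Idi1 went from 281±24.6 to 69.9±2.73 CPM (SD, n = 3), Insig1, the sterol sensor of the pathway, from 115±24.2 to 25.4±1.93 CPM, and Mki67 from 30.8±34.3 to 2.69±0.807 CPM, while Lcn2 rose from 781±229 to 2192±12.7 CPM and Trib3, a pseudokinase, from 54.2±34.1 to 201±22.5 CPM. Of the cholesterol list, 22 of 23 fell and 1 rose (0 rose without day 7 replicate C), with a median log2 fold change of -1.43. Of the mitosis list, all 28 fell (median -3.23). Of the replication list, 22 of 25 fell (median -1.64). Of the stress response list, 13 of 25 rose (Slc7a11 from 24.7±14.4 to 87.1±13.9 CPM). Of the glycolysis list, 8 of 18 fell (Ldha, lactate dehydrogenase, from 2305±1020 to 1015±55.7 CPM). Of the endothelial markers, 11 of 15 fell (adjusted over the list alone, 25 lower in DNA replication, 16 higher in stress response, 11 lower in glycolysis and 1 higher and 14 lower in endothelial markers), with Pecam1 going from 5.40±5.33 to 0.430±0.0363 CPM. Without day 7 replicate C the day 7 means of Mki67 and Pecam1 were 11 and 2.32 CPM (n = 2). For the cholesterol list, mitosis list, replication list, stress response, glycolysis list and endothelial markers, camera (BH) gave adjusted p = 5.4e-74, 2.77e-29, 4.37e-18, 2.4e-07, 3.81e-05 and 3.45e-10, and p = 0.00407, 0.355, 0.372, 0.0466, 0.857 and 0.355 with an estimated correlation.

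Among the largest changes after day 7, Igfbp2 rose from 50.5±37.2 to 635±126 CPM (SD, n = 3), Ccnd2, a cyclin, from 30.04±16.0 to 241±23.9 CPM, and Cdsn from 1.78±0.655 to 16.7±2.11 CPM, while Gldc, the glycine decarboxylase, fell from 16.6±25.6 to 1.02±0.279 CPM (adjusted p = 0.0213, edgeR quasi-likelihood, BH, but 0.479 without day 7 replicate C, 0.0652, 0.0804 and 0.0761 without day 14 replicates A, B or C, and 0.000291 to 0.479 over the alternatives) and Birc5, survivin of dividing cells, from 36.0±41.7 to 2.50±0.353 CPM. Without day 7 replicate C the day 7 means of these last genes were 1.83 and 12 CPM (n = 2). In all 950 genes were higher and 1399 lower on day 14 than on day 7. Without day 7 replicate C, 1111 genes were higher and 1784 lower, without day 14 replicate A 588 and 763, without day 14 replicate B 477 and 796, and without day 14 replicate C 444 and 770. Without day 7 replicate C, 16 members of the glycolysis list, 19 of the hypoxia list and 19 of the respiratory chain list were lower, against 8, 3 and 5 with it, and the median of mitosis was -1.93 and that of DNA replication -0.71. The mesenchymal list had 0 higher and 7 lower, but 5 higher and 4 lower without it. With library sizes alone 1554 genes were higher and 1105 lower (58.4% higher, against 40.4%), and by limma on log2(TPM + 1) 1697 and 621 (73.2%). A fit of only the 6 libraries of these days called 127 higher and 92 lower, and there Birc5, Gldc, Igfbp2, Ldha, Mki67, Pecam1, Slc7a11 and Trib3 had adjusted p between 0.0871 and 0.19 (edgeR quasi-likelihood, BH).

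Some changes of day 1 turned back later. Krt5, a keratin of basal epithelial cells, had 0.0753±0.0770 CPM on day 0, 19.6±4.38 CPM on day 1, 1.97±0.850 CPM on day 4 and 0 counts on day 14 (SD, n = 3). Prl2c2 went from 0 counts on day 0 to 306±97.4 CPM on day 4 and 1.57±0.234 CPM on day 14, and Sprr2h from 110.3±19.8 CPM on day 1 to 0.0331±0.00232 CPM on day 14, both with reads that could be split among copies. In the other direction Klf15, a glucocorticoid-induced transcription factor, had 199±52.3 CPM on day 0, 9.52±3.21 CPM on day 1, 2.91±0.465 CPM on day 4 and 33.7±3.01 CPM on day 14, Dhrs3 154±17.5 CPM, 9.28±3.66 CPM, 3.86±0.580 CPM and 84.8±26.7 CPM on the same days, and Lrrn1 9.13±1.24 CPM, 0.538±0.163 CPM, 3.63±1.08 CPM and 145±10.3 CPM. By comparisons that share no library, 565 genes were higher on day 1 than on day 0 and lower on day 14 than on day 4, each by at least 2-fold at an adjusted p of 0.05 (edgeR quasi-likelihood, BH), where independent lists of 3790 and 1764 genes among 18754 would share 356. The opposite course was taken by 1214 genes, where independent lists of 4749 and 2561 would share 649. Limma on log2(TPM + 1) gave 286 and 530, and glmTreat 201 and 430.

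**Figure D5:**
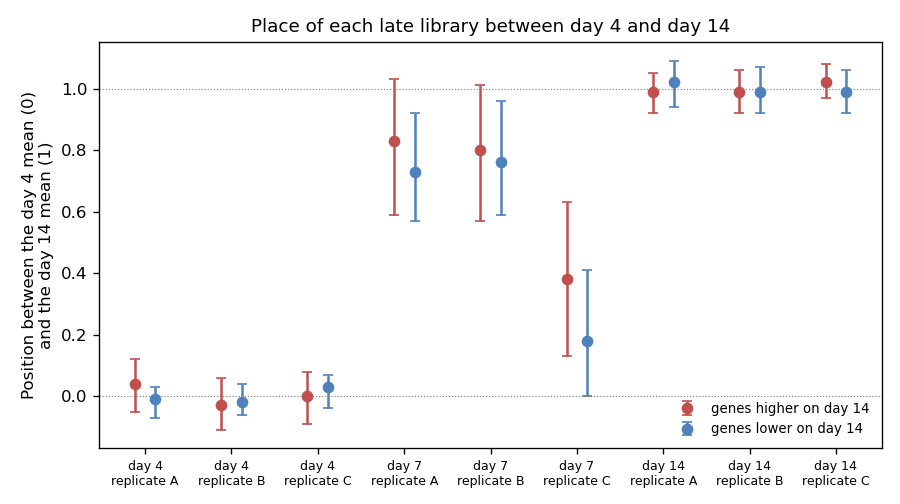
Position of each library of days 4, 7 and 14 between the day 4 mean (0) and the day 14 mean (1), as the median over the 2508 genes higher and the 1718 lower on day 14 (vertical axis, no unit; libraries on the horizontal axis), with error bars for the quartiles over genes. Day 7 replicates A and B lie at 0.83 and 0.80 over the genes higher on day 14, and day 7 replicate C at 0.38.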

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

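Counts of list members and 2-fold changes and means of day 7 without day 7 replicate C were chosen after the data were seen, and the other alternatives were planned. With DESeq2 size factors all 28 counts and distances stayed within 1.5 times or 1 SD, and 157 of 159 list results and all 220 gene results kept their direction and side of the threshold, as did 219 gene results with the DESeq2 Wald test, where all 21 counts stayed within 1.5 times. The balance of genes higher and lower turned under 1 or more alternatives in each comparison but day 7 against day 4, as with those size factors on days 2, 4 and 14 against day 0 (6745 and 7017, 6800 and 7140, and 6352 and 6456) and from day 2 to 4 (3881 and 3830, and 4435 and 4192 with only the libraries of these days, and 3665 and 3171 by limma on log2(TPM + 1)). Each library left out kept 2821 of 2862 list results and 3932 of 3960 gene results. An estimated correlation left 40 of the 238 list tests passed by camera, and fry changed 29 of 159 list results, 24 of which newly passed. The labels do not say what the replicate letters mean, and they were not taken as pairs: 8 of 45 pairs of libraries with the same letter had r over 0.1, and 12 of 18 libraries correlated best with a library of their letter, where letters with no meaning would give 6. The replicate block moved no count by over 1.5 times (6183 higher and 6950 lower on day 1 against day 0, 963 and 1291 on day 14 against day 7). It changed the calls of Vcam1 on day 14 against day 0 (adjusted p = 0.0536, edgeR quasi-likelihood, Benjamini-Hochberg) and, by camera, of S3 segment and macrophage markers on day 1 (0.0472 and 0.0112) and p53 targets from day 2 to day 4 (0.0491), and no other call among the list and named gene results.

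Against a fold of 2, which a change must exceed by its error, glmTreat called 2574 genes higher and 3419 lower (6208 and 6949 against no change) on day 1 against day 0, 3336 and 3726 (7289 and 6619) on day 2, 3380 and 4112 (7145 and 6895) on day 4, 2998 and 3270 (7060 and 6028) on day 7 and 2856 and 3297 (7007 and 6026) on day 14. From day 1 to 2 it called 407 and 644 (3186 and 3283), from day 2 to 4 324 and 881 (3633 and 4138), from day 4 to 7 310 and 74 (4122 and 2985), from day 7 to 14 29 and 75 (950 and 1399), and turning back 201 and 430 (565 and 1214). Limma on log2(TPM + 1) had 4559, 3877, 3950, 3147 and 2891 genes lower on days 1, 2, 4, 7 and 14 against day 0 and 10791 higher on day 14, 5288 higher and 1832 lower from day 1 to 2, 1697 and 621 from day 7 to 14, and 286 and 530 turning back. On log2(TPM + 0.1) the first 5 were 4595, 3836, 3957, 3111 and 2840, with 10923 higher on day 14, 5376 and 1775 from day 1 to 2 and 664 lower from day 7 to 14. Without the filter on TPM, 10842 and 11966 were higher on days 7 and 14, 5063 and 1930 from day 1 to 2, 1745 and 505 from day 7 to 14, and 276 and 512 turned back. With library sizes alone there were 5492 and 2185 from day 1 to 2 and 1554 higher from day 7 to 14, and without the count filter 610 higher there. Fits of the 6 libraries compared called 6713 and 6772 on day 14 against day 0. From day 4 to 7 they called 1918 and 1691, and from day 7 to 14 127 and 92. With 1 library left out that last step ranged from 444 higher (without day 14 replicate C) and 763 lower (without A) to 1111 and 1784 (without day 7 replicate C).

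Distances on days 0, 1, 2, 4, 7 and 14 were 0.2833, 0.8959, 1.034, 1.124, 1.039 and 1.05 with no filter, which adds genes of few counts, and 0.3146, 1.329, 1.565, 1.773, 1.626 and 1.642 with a prior count of 0.5. With library sizes alone those of days 2 to 14 were 1.508, 1.673, 1.563 and 1.606, and with a library left out day 0 ranged from 0.2677 to 0.3244 and day 14 from 1.476 to 1.489. Directions turned as follows, and the causes were not tested. Endothelial markers on day 1 had medians of 0.18 with the replicate block, 0.11 with DESeq2 size factors and -0.12 to 0.34 with a library left out (camera turned up in the first pair and without 7 of the 18 libraries). Camera turned for the lymphocyte markers of day 14, at medians of -4.33 with DESeq2 size factors and -4.48 to -3.7 with a library left out. Mesenchymal and cytoskeletal medians ran from -0.47 (without day 7 replicate A) to 0.22 (without C) on day 14 against day 7, and from -0.19 (without C) to 0.54 (without A) on day 7 against day 4. Vcam1 on day 1 was at 0.29 with library sizes alone, 0.01 without mitochondrially encoded genes, 0.17 with only days 0 and 1, 0.37, 0.54 and 0.37 by limma, and -0.1 (without day 1 replicate A) to 0.08 (without C). A gene with 0 counts on a day allows up to 3 counts over its libraries, which limits falls near 0 to bounds.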

Other observations

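The tests of gene families that share a name and those of day 7 replicate C were chosen after the results had been seen. The 10 families were tested by camera with Benjamini-Hochberg adjustment (BH) over the families of a comparison, and the directions given held under each scaling run. On day 1 against day 0, small proline-rich proteins and keratins, structural proteins of stratified and simple epithelia, rose: 9 of 11 and 11 of 16 rose, and 0 and 1 fell. Reads of the former can be split among near-identical copies. Of the cytosolic ribosomal proteins 77 of 81 rose (Rpl3 from 226±14.9 to 408±19.2 CPM, SD, n = 3), of the clade B serpins 13 of 15 rose and 1 fell, and of the Hox genes 23 of 31 fell (Hoxb6 from 23.4±2.67 to 7.35±0.117 CPM). For these 5 families in that order, camera (BH) gave adjusted p = 2.98e-07, 7.8e-06, 7.02e-13, 0.0121 and 0.0038, and p = 0.0263, 0.0263, 0.332, 0.0524 and 0.286 with an estimated correlation.

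On day 14 against day 0, 8 of 11 Wnt ligands rose and 2 fell, 12 of 14 cadherins rose and 2 fell (Cdh3, P-cadherin, from 9.09±0.886 to 158±7.19 CPM, SD, n = 3), and 18 of 21 vacuolar ATPase subunits fell and 1 rose (Atp6v1a from 886±24.1 to 356±7.68 CPM). From day 4 to day 7, 71 of 81 ribosomal proteins fell (median -0.49), as did 32 of 38 proteasome subunits while 4 rose (median -0.47), and 6 of 11 small proline-rich proteins fell, or 9 without day 7 replicate C. For these 6 results camera (BH) gave adjusted p = 0.00171, 0.019, 5.37e-05, 1.26e-25, 6.59e-14 and 9.04e-08, and p = 0.158, 0.16, 0.16, 0.153, 0.0874 and 0.0392 with an estimated correlation. Claudins passed in no comparison, with adjusted p between 0.082 and 0.568.

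The 36 proximal tubule transporters lay far below day 0 on day 14. Non-epithelial cells overgrowing the tubule cells would lower epithelial genes alike. The median of the general tubule epithelium list lay 10.97 log2 units above the transporters' (quartiles 1.41 to 3.08 over 14 genes, against -11.45 to -7.19). This argues against that. Outgrowing distal nephron cells that kept their markers would raise these. The pooled median of 43 distal genes was -6.13 (quartiles -10.64 to -1.74), which argues against that. Distal cells that lost them, parietal or thin limb cells (most markers rose) and loss of transporter RNA within tubule cells stay open and were not tested.

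Day 7 replicate C had Vim at 455 CPM, against 50.3 and 35.1 in day 7 replicates A and B, and Pax8 at 149 CPM, against 327 and 354. A day 4 library under a day 7 label would sit near 0 between day 4 and day 14, as the day 4 medians of -0.03 to 0.04 did, but its median position over genes higher on day 14 was 0.38 (quartiles 0.13 to 0.63), which argues against that explanation. Over the genes lower on day 14 it was 0.18 (0 to 0.41), closer to the day 4 medians of -0.02 to 0.03. RNA mixed from only the other 17 libraries cannot exceed the highest of them. But 45 genes at 10 CPM or more stood at least 2-fold above each (at most 9 in any other library), which argues against it. Such RNA mixed into that of C stays open. Fibroblasts in that culture cannot be told apart from other sources, since Col1a1, Col1a2 and Col3a1, all also on the matrix list, summed to 75.4 CPM, below the 101 and 94.2 CPM of replicates A and B and above the 16.7 to 25.5 CPM of day 4, while 12 of the 15 fibroblast and pericyte markers were higher in C than in both (42.1% of all tested genes were), such as Pdgfrb at 12.8 CPM, against 5.29 and 6.16, and 3 were lower, such as Notch3 at 6.38 CPM, against 21.8 and 22.5. The design names no testable difference between replicates of a day.

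The calls of day 14 against day 0 could depend on mitochondrial transcripts taking counts, but leaving them out moved the counts at most 1.06-fold, which argues against that. Time in culture, which the labels name, stays open.

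Each comparison of 6 libraries has 10 splits into 3 and 3, too few for a share under 0.05. By edgeR quasi-likelihood, the real split called 13157, 13908, 14040, 13088 and 13033 genes for days 1, 2, 4, 7 and 14 against day 0, with 0, 0, 0, 1 and 0 in the highest other split. The steps to days 2, 4, 7 and 14 had 6469, 7771, 7107 and 2349 genes, with 0, 0, 1064 and 1 in the highest other. The 3 other splits of days 4 and 7 that called 676 to 1064 genes put day 7 replicate C with libraries of day 4, which points to a structure of the samples. Among 100 groupings of the 18 libraries, only the real one reached 16839 genes with any difference among days (highest other 481). For the 565 and 1214 that turned back each other grouping gave 0, and independent lists would share 356 and 649. The other groupings mix days, which leaves few or no calls, so neither count decides on chance.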
